A study of Xenopus tropicalis with 15 samples.

How the data were processed

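The series holds 15 libraries from the middle brain of wild-type Xenopus tropicalis tadpoles. Per the labels, 12 are MethylCap libraries, 3 at each of NF50, NF56, NF62 and NF66, and 3 are inputs, 1 each at NF50, NF56 and NF62. Per the labels' protocols, DNA was sheared by sonication to about 400 bp and sequenced as 50-bp single reads on a HiSeq 2000. Capture by a methyl-binding protein favours DNA dense in methylated CpG, so the values measure enrichment and not the methylation level of a base. Per the submitters' processing notes, HISAT2 2.1.0 was among the tools used. The deposited lists carry the naming of the caller PePr, whose version and options, like the genome build, are not given in the sources used here.

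The deposited peak lists give for each region the authors' score, which is the fold column multiplied by a constant, with 2 constants in the NF62 list. The fold in the deposited peak lists is a ratio over background as the caller gave it. In the authors' deposited DMR lists the fold is a signed ratio between the stages, never between -1 and 1. The p-value and q-value of each region are those the authors deposited; peak lists end at a p of 1e-05 and DMR lists at an unadjusted p of 0.05. A score, fold, p-value or q-value was mainly used to describe, rank or filter regions within its own list. Peak folds of different stages were set side by side as medians of the lists, over shared peaks, and at scaffold_477 and scaffold_709. The folds, p-values and q-values of DMRs were also filtered or ranked across the lists of several comparisons. The numbers in the deposited peak names run higher than the number of peaks (to 123188 for NF50), for a reason not known, and a few names occur more than once. Among the DMR lists, NF62 against NF56 alone has repeated names, carried by 5278 of its regions (5.07%) at different positions; how that list was put together is not given in the sources used here. In all 6 DMR lists the group in the name and the sign of the fold went together for every region.

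The sign of a DMR was read from the region names, which carry PePr's group 1 or 2, and which stage is group 1 was settled from the data: of DMRs lying in a peak of only 1 of the 2 stages, 93.6% to 94.9% had the direction that follows if group 1 is the first-named stage. All directions rest on this reading, and because it was taken from overlap with peaks, DMRs that match gained and lost peaks are not separate evidence for it.

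All lists were read onto windows of 100 bp with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Regions count as overlapping at 1 bp or more. A scaffold was taken to end at the last listed base. Overlap between stages was set beside 100 random circular shifts, and the sharing of DMRs beside 100 random placements in the union of all peaks and DMRs. Shares carry exact binomial 95% intervals where given; these cover counting error only, since neighbouring regions are not independent. The scripts were tested on simulated lists: all 11189 removed and 5000 added peaks were recovered from the 111896 NF50 peaks, and in the test of NF56 against NF50 with NF66 against NF62 (83923 regions) independent lists gave 0.9958 of the chance sharing and a planted share of 30.03% came back as 30.38%. The independent list was itself drawn by the random placement, so the value of 0.9958 was built in and checks the code alone. It does not show that unrelated DMR lists would share as much as random placement gives. The simulated values for comparisons with and without a common stage come from 1000000 features in groups of 3 libraries with equal normal spread and no difference. Each feature was called at a 2-sided p under 0.05, and the simulation was added after the data were examined.

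No test between stages was made from the lists, since the deposited lists pool the 3 libraries of a stage, and the authors' p and q values stand for the replicate test. The depth of each library is unknown, and with it the smallest difference that could be seen. Splits of the libraries, leave-one-out fits and a replicate block need values per library and were not run. The groups, the comparisons of lists and their first set of alternatives, and the rule for named regions were fixed before the data were examined. The threshold of a q under 0.05, on which the words rose and fell rest, was chosen afterwards, as were the further settings named below and most tests of the closing section, where they are listed. That rule names, for each comparison and direction, the 3 regions with the smallest authors' p, ties by width; the text gives some of them. The text also names scaffold_9, scaffold_3 and scaffold_5 as the extremes of a range.

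The planned results on genes, promoters, gene lists (thyroid hormone signalling and the DNA methylation machinery among them), CpG density and repeat content need sequence or annotation of the build in use and were not run. Coordinates are on scaffolds numbered up to 19835, of which 8608 hold a region, and the gene table at hand belongs to the assembly UCB_Xtro_10.0, so none of its positions was used. In place of chromosomes, the 20 longest scaffolds and 3 classes of scaffold length were used. Alternatives tried were a p of 1e-10 or smaller, merging within 500 bp, 50% overlap, counting by bases, and DMRs in peaks only. Added after the data were examined were a q under 0.05, a p of 0.001 or smaller, a p of 1e-10 or smaller for the counted peaks only, and NF62 against NF56 without repeated names; scaffolds ending at 1 Mb or beyond stand in for the planned chromosome-scale sequences.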

Results

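DNA methylation was profiled in the brain of Xenopus tropicalis tadpoles at 4 Nieuwkoop and Faber (NF) stages of metamorphosis, in tissue holding the preoptic area, hypothalamus and thalamus. NF50 is a premetamorphic stage, NF56 belongs to prometamorphosis, NF62 to metamorphic climax, when thyroid hormone in the blood is near its peak, and NF66 is the end of metamorphosis. Methylated DNA was captured and sequenced (MethylCap-seq) in 3 libraries per stage, 12 in all, and 3 input libraries of uncaptured DNA came from NF50, NF56 and NF62. The comparisons ask where methylation of this brain region differs between stages. The values analysed are 4 lists of methylated regions (peaks), 1 for each stage, and 6 lists of differentially methylated regions (DMRs), 1 for each pair of stages. Each list takes the 3 libraries of a stage together, so the files show no value and no depth of a library, and the authors' p and q values are the sole measure of the spread between libraries. The submitters' design text calls the 3 libraries of a stage biological replicates; how many animals went into each is not stated in the sources used here. Regions are placed on numbered scaffolds of a genome build not given in the sources used here, and they are named by position because no gene annotation of that build was used.

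Methylated regions were similar in number at NF50, NF56 and NF62 and fewer at NF66. The lists held 111896 peaks at NF50, 112019 at NF56, 110870 at NF62 and 106073 at NF66. They covered 64.9, 65.3, 64.6 and 61 Mb in the same order. Peaks had a median width of 500 bp at every stage, with an interquartile range of 300 to 700 bp. The authors' fold of a peak over background, a value of the peak within its own list, had a median of 15.2 at NF50, 15.5 at NF56, 13.9 at NF62 and 14.9 at NF66. With 1 pooled list per stage, the difference of NF66 has no replicate check, and as no NF66 input is among the labels, the background behind the NF66 peaks is unknown, which bears on the lower count and on the losses to NF66 alike. Keeping only peaks with an authors' p of 1e-10 or smaller left 59858 peaks at NF50, 59958 at NF56, 59266 at NF62 and 55309 at NF66.

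Most methylated regions were common to the 4 stages. Merging the 4 lists gave 122358 regions, and 96941 of them (79.23%) had a peak at every stage. Regions with a peak at 1 stage alone numbered 3173 for NF50, 2997 for NF56, 2681 for NF62 and 1204 for NF66. A further 3754 regions had a peak at NF50, NF56 and NF62 and none at NF66, compared with 1614 that lacked a peak at NF50 alone. Between pairs of stages, 90.5% to 96.1% of peaks overlapped a peak of the other stage by at least 1 bp, and the base-pair Jaccard index lay between 0.852 (NF50 and NF66) and 0.868 (NF50 and NF56). Lists shifted at random along their scaffolds overlapped by 9.92% to 10.54% on average over 100 shifts. The overlap is a description of lists and carries no replicate error.

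Losses of peaks outnumbered gains after climax. From NF62 to NF66, 9736 peaks were lost and 4449 gained, and from NF50 to NF66, 10612 were lost and 4558 gained. The earlier steps were closer to balance, with 7111 gained and 6737 lost from NF50 to NF56, and 6283 gained and 7448 lost from NF56 to NF62. Of the peaks lost from NF62 to NF66, 46.3% held a DMR lower at NF66 and 0.8% a DMR higher at NF66, compared with 31.5% and 13.5% of the NF62 peaks that were not lost. Of the peaks gained in that step, 28.7% held a DMR higher at NF66 and 2.9% a DMR lower there, compared with 14.2% and 29.4% of the NF66 peaks that were not gained. The DMR directions were read from overlap with peaks of the same libraries, so this match was largely built in and is no separate evidence. Peaks gained or lost were narrow, with a median width of 200 bp, and their median p in the authors' list lay between 2.52e-06 and 3.55e-06, close to the list's limit of 1e-05. From NF62 to NF66, the peaks not lost had a median width of 600 bp and those not gained 500 bp, so the shares compared are not matched for width. Among peaks with a p of 1e-10 or smaller, 206 had no overlap at all in the NF66 list after NF62 and 116 were gained in that step.

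**Figure D1:**
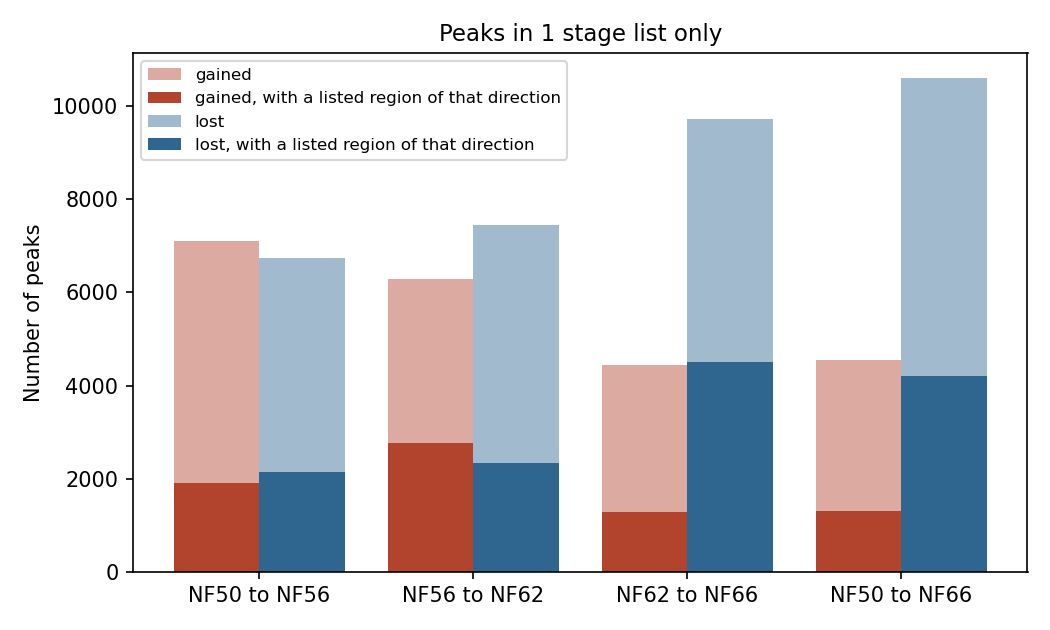
Number of peaks (vertical axis) present in the list of 1 stage and absent from the other, for 4 steps between stages; red bars are gained and blue bars lost, and the darker part of each bar is the number that held a DMR of the matching direction. The largest counts are the 9736 and 10612 peaks lost on the way to NF66.

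The 6 DMR lists held 587850 regions in all, and 557 of them (0.095%) had a q under 0.05. The lists extend to an unadjusted p of 0.05, and between 98.00% and 99.89% of the regions in a list had a q of 1. If p-values were spread evenly up to that limit, 20% of a list would have a p under 0.01, and the share found was 19.4% for NF56 against NF50 and 24.0% to 26.3% for the other comparisons. Shares with a p of 0.001 or smaller were 2.45% for NF56 against NF50 and 3.75% to 4.61% for the others, where an even spread gives 2%. Only regions with a q under 0.05 are described here as having risen or fallen.

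**Figure D2:**
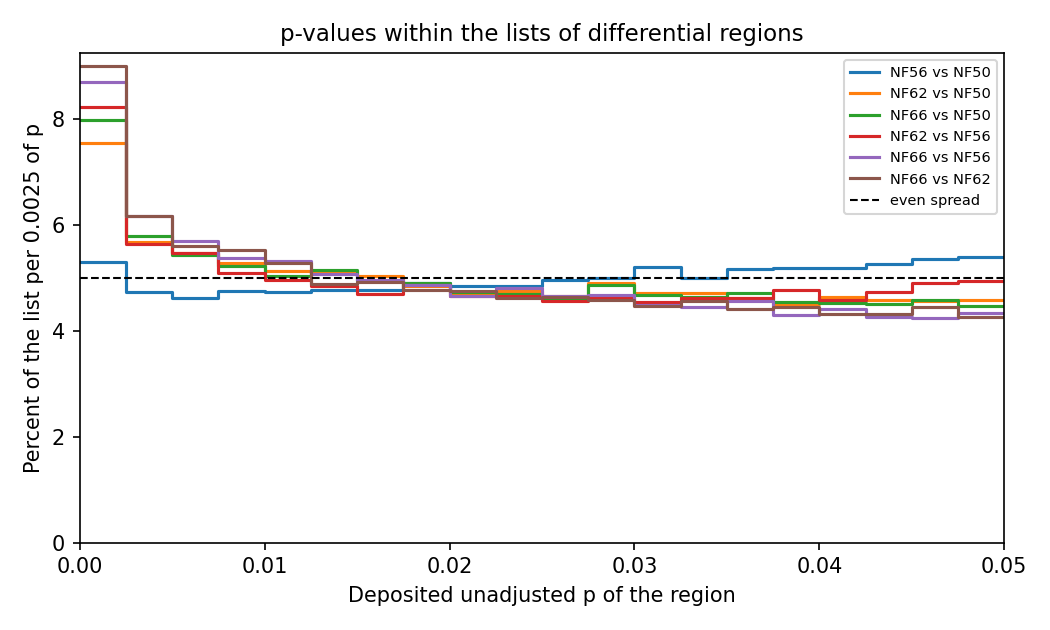
Share of each DMR list in percent (vertical axis) per 0.0025 of the authors' unadjusted p (horizontal axis), with 1 line for each of the 6 comparisons and a dashed line at the 5% that an even spread gives. NF56 against NF50 is nearly flat, with 5.29% in the first interval and 5.4% in the last, and NF66 against NF62 begins at 9.01% and ends at 4.26%.

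Between premetamorphosis and prometamorphosis few regions passed the q threshold. At a q under 0.05, 3 regions rose and 16 fell from NF50 to NF56. The first of those that fell, scaffold_1255 from 42001 to 42400, was 3.89-fold lower at NF56 (q = 5.57e-10) in the authors' deposited table. Next came scaffold_1755 from 6801 to 7300, 1.94-fold lower (q = 4.46e-06), and scaffold_32 from 3195501 to 3195900, 5.17-fold lower (q = 6.51e-05), in the authors' deposited table; the latter had no peak at NF56 and peaks at the 3 other stages. The regions that rose were scaffold_255 from 1141601 to 1142000, 1.52-fold higher, scaffold_77 from 1342001 to 1342400, 4.23-fold higher, and scaffold_2350 from 8001 to 8900, 1.31-fold higher, with q values of 0.00345, 0.00345 and 0.012 in the authors' deposited table. The whole list held 83923 regions, of which 44.3% were higher at NF56.

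From premetamorphosis to climax, 45 regions rose and 36 fell. The leading gain lay on scaffold_477 from 852501 to 853600, 5.77-fold higher at NF62 than at NF50 (q = 6.37e-09) in the authors' deposited table, where neither NF50 nor NF56 had a peak. Losses were led by scaffold_698 from 419501 to 420200, 2.57-fold lower (q = 1.51e-07), scaffold_57 from 3035801 to 3036500, 2.54-fold lower (q = 4.17e-07), and scaffold_73 from 1052301 to 1052700, 5.40-fold lower (q = 0.00023) in the authors' deposited table. The region on scaffold_73 had peaks at NF50 and NF56 and none at NF62 or NF66. The regions on scaffold_698 and scaffold_57 had the same width, 700 bp, and near-equal folds in most other comparisons of the authors' deposited table. At NF66 they were 1.56-fold and 1.58-fold lower than at NF50, and 1.71-fold and 1.75-fold higher than at NF62. For NF66 against NF56, only scaffold_57 had a listed DMR. Whether they are separate changes or 1 repeated sequence cannot be told without sequence. The full list held 97071 regions, 51.9% of them higher at NF62, and this share turned to 47.1% among the 52442 regions that overlapped a peak, compared with 57.5% of the regions outside all 4 peak lists.

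Between premetamorphosis and the end of metamorphosis, more regions fell than rose. At a q under 0.05, 45 regions were lower and 22 higher at NF66. The region on scaffold_129 from 1863901 to 1864800 was 3.05-fold lower (q = 1.54e-13) in the authors' deposited table, and scaffold_251 from 1223701 to 1224200 was 2.26-fold lower (q = 2.44e-06) there. The scaffold_477 region was 6.85-fold higher at NF66 (q = 2.02e-17) in the authors' deposited table. A short scaffold, scaffold_15990, held a region from 1501 to 2900 that was 1.41-fold higher (q = 3.3e-06) in the authors' deposited table. In the full list of 98798 regions, 35.9% were higher at NF66.

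Prometamorphosis and climax gave the most regions past the q threshold, mostly gains. From NF56 to NF62, 185 regions rose and 35 fell. Among the gains, scaffold_15990 from 1501 to 3000 was 1.67-fold higher (q = 2.38e-13) and the scaffold_477 region 4.92-fold higher (q = 1.14e-11) in the authors' deposited table. The losses with the smallest p were wide regions of small change: scaffold_612 from 95201 to 99000 was 1.24-fold lower (q = 2.35e-18), scaffold_1804 from 18701 to 19900 was 1.27-fold lower (q = 6.65e-17), and scaffold_3494 from 5101 to 7700 was 1.24-fold lower (q = 3.51e-14) in the authors' deposited table. Over the 96941 regions with a peak at every stage, the median ratio of the peak fold at NF56 to that at NF62 was 1.112. That ratio compares folds over background from separate lists, unlike the fold of a DMR. A shift common to all peaks may be part of such small changes, and it would make regions in a peak mostly lower at NF62. Of the listed regions in a peak, however, 54.0% were higher at NF62, and 71.2% of those with a p of 0.001 or smaller. These shares argue against such a shift for listed regions in peaks as a set. For the small changes themselves it was not tested. Of the full list of 104045 regions, 60.0% were higher at NF62, and the share rose to 84.1% of the 220 regions with a q under 0.05. The full-list share was 54.0% for regions in a peak and 66.5% for those outside all 4 peak lists, where it was 86.2% at a p of 0.001 or smaller. In this list alone, 5278 regions carried a name used for more than 1 region, and 0 of these had a q under 0.05.

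From prometamorphosis to the end of metamorphosis, 61 regions rose and 58 fell. The scaffold_477 region was 5.78-fold higher at NF66 than at NF56, with the smallest q of any region that rose, 6.82e-19, in the authors' deposited table. The scaffold_4370 region from 6801 to 7600 was 1.19-fold lower (q = 7.21e-18) and scaffold_934 from 64801 to 65800 was 1.17-fold lower (q = 6.98e-11) in the authors' deposited table. The scaffold_612 region, from 95401 to 99000 in this comparison, was again lower, by 1.21-fold (q = 4.24e-15), in the authors' deposited table. Beside these small changes, the median ratio of the peak fold at NF56 to that at NF66 was 1.061 over regions with a peak at every stage, with the NF66 background unknown. Of all 100996 regions 39.9% were higher at NF66, as were 35.9% of the 4446 with a p of 0.001 or smaller. Among the 119 with a q under 0.05 the share was 51.3% (exact binomial 95% interval 41.9% to 60.5%), which gives no direction.

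From climax to the end of metamorphosis, listed regions were mostly lower at NF66, and few passed the q threshold. At a q under 0.05, 29 regions fell and 22 rose. The regions that fell included scaffold_709 from 489701 to 490200, 3.74-fold lower (q = 1.33e-05), and scaffold_673 from 216501 to 217100, 4.56-fold lower (q = 0.000109), in the authors' deposited table. The scaffold_673 region had a peak at NF50, NF56 and NF62 and none at NF66, while scaffold_709 had a peak at every stage, whose fold in the authors' separate peak lists was 11 at NF62 and 18.2 at NF66, the opposite order to the DMR. The 2 measures also differed more widely in this comparison. Over regions with a peak at every stage, the median ratio of the NF66 peak fold to that at NF62 was 1.049. Of the listed regions in a peak, 29.7% were higher at NF66. The NF66 background is unknown, and the cause was not tested. Scaffold_1377 from 46101 to 47400 was 1.68-fold higher at NF66 (q = 2.29e-07) in the authors' deposited table. Over all 103017 regions, 30.5% were higher at NF66, and the share fell to 18.5% of the 4747 regions with a p of 0.001 or smaller and was 43.1% of the 51 with a q under 0.05 (exact binomial 95% interval 29.3% to 57.8%, which covers counting error only).

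**Figure D3:**
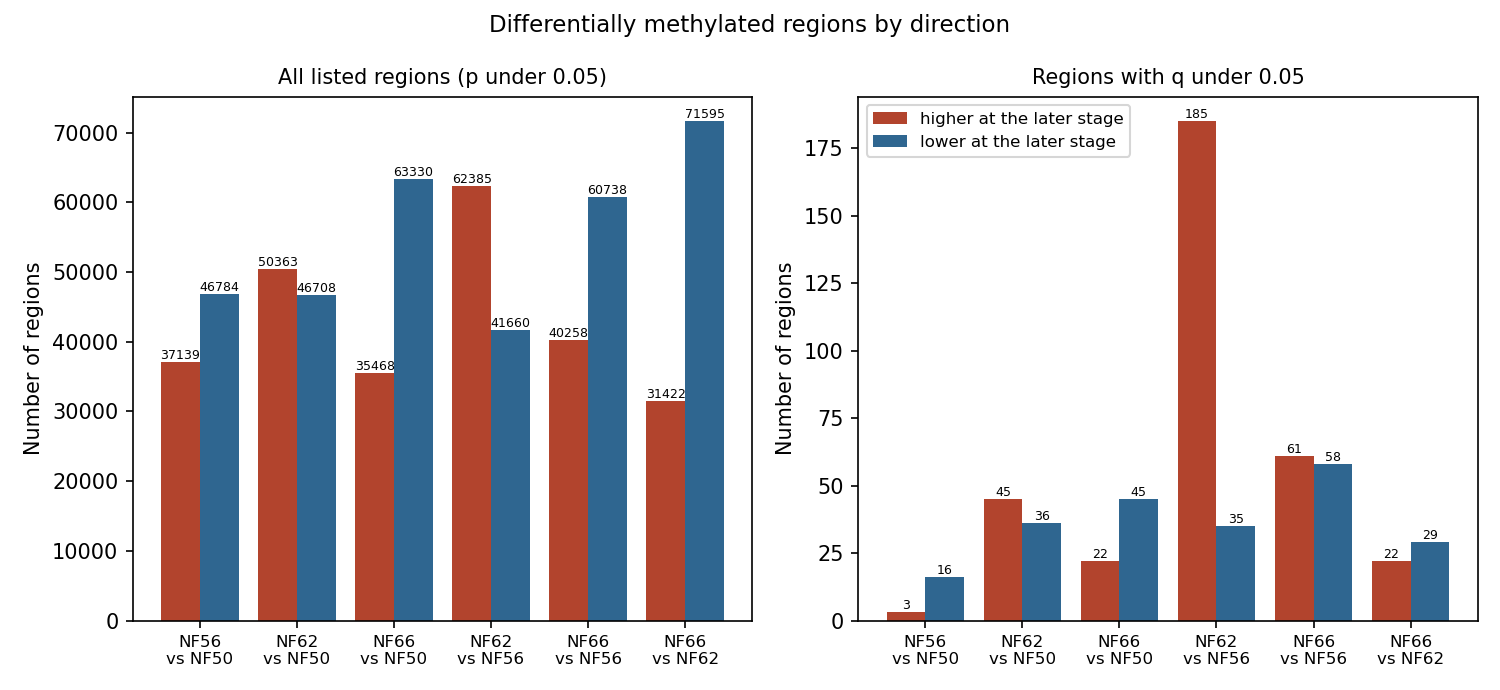
Number of DMRs (vertical axis) higher (red) and lower (blue) at the later stage for each of the 6 comparisons, over all listed regions on the left and over regions with a q under 0.05 on the right. In the full lists the 3 comparisons with NF66 have more lower than higher regions, and at a q under 0.05 NF62 against NF56 stands out with 185 higher and 35 lower.

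The scaffold_477 region was higher at the later stage in the 4 comparisons of NF62 or NF66 with NF50 or NF56. It spanned 1100 bp and had a peak at NF62, with a fold over background of 2.87, and at NF66, with one of 3.57. For NF66 against NF62 the authors' deposited table listed a 1.37-fold higher value there, with an unadjusted p of 9.18e-05 and a q of 1, so it did not pass the threshold. No DMR was listed there for NF56 against NF50.

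**Figure D4:**
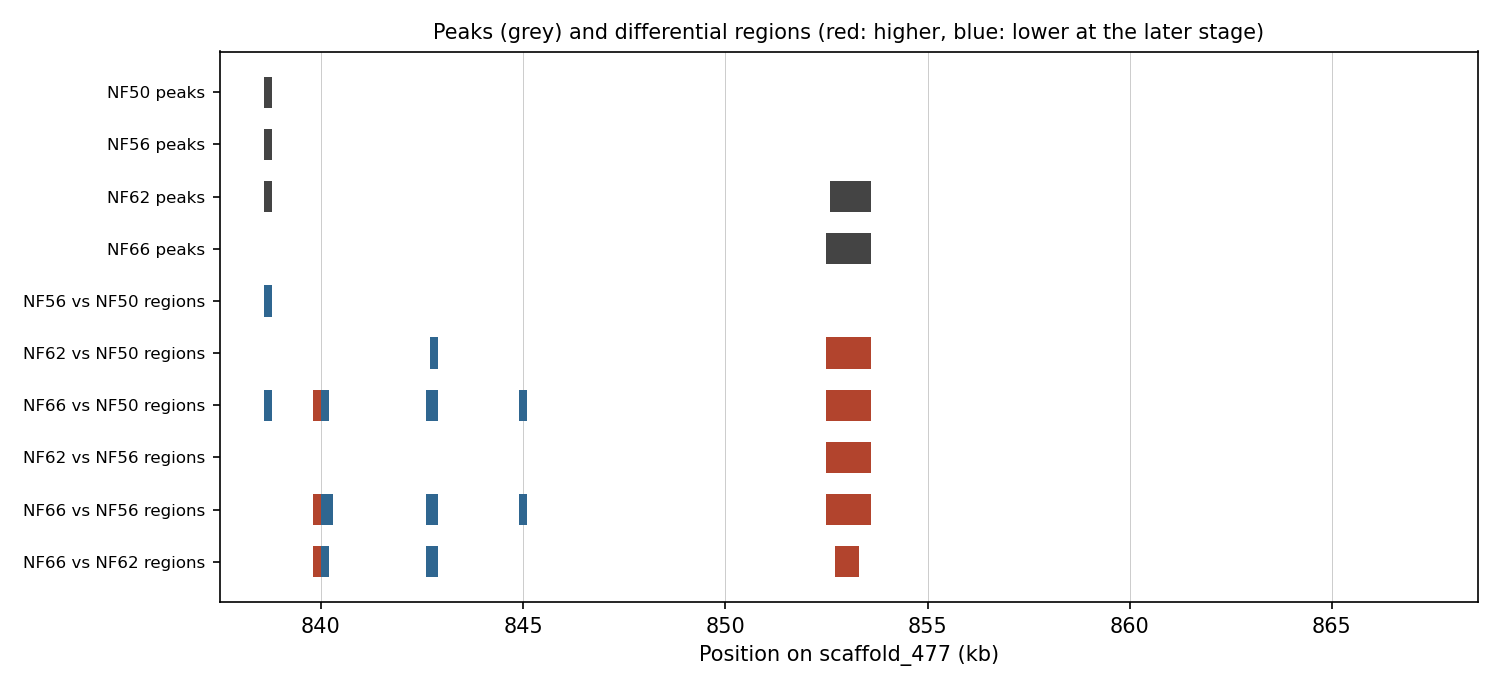
Map of scaffold_477 around the region from 852501 to 853600, with position in kb on the horizontal axis; grey bars are the peaks of each stage and coloured bars the DMRs of each comparison, red for higher and blue for lower at the later stage. Peaks stand at the region in the NF62 and NF66 rows, and red bars in the 4 comparisons of these stages with NF50 or NF56 and in NF66 against NF62.

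Across the comparisons, 422 merged regions had a q under 0.05 in at least 1 list, 103 of them in 2 or more and 7 in 4. Comparisons that share a stage share its libraries. For such pairs, 35.2% to 42.2% of the regions of the first list overlapped a region of the second, and where the common stage had the same role the direction was the same in 89.9% to 94.5% of them. Simulated groups of 3 libraries with no difference, set against a common group, shared 18.6% of their calls, with the same direction in 99.9%, so a common direction there is no evidence of a stage difference. The simulated features were single and independent, and without a common group they shared 5.0%. The simulated sharing is therefore no baseline for the overlap of listed regions. Random placement in the union of peaks and DMRs gave a sharing of 28.37% to 32.07% for these pairs, and part of the excess may come from the shared libraries. Comparisons without a common stage shared 25.4% for NF56 against NF50 with NF66 against NF62, 26.9% for NF62 against NF50 with NF66 against NF56, and 26.7% for NF66 against NF50 with NF62 against NF56, which is below the 31.06%, 30.94% and 31.41% of random placement in the same order. The area of placement is itself partly made of DMRs, which sets the chance value high. For regions inside peaks, placed at random inside peaks, the sharing was 1.08, 1.13 and 1.15 times that of chance in the same order. Whether these pairs shared fewer or more regions than chance thus depended on the area. Directions in the first of these pairs were the same in 51.3% of shared regions, where the margins give 52.6%, in the second in 58.4% (49.6% from the margins) and in the third in 56.4% (47.3%). Among regions with a p of 0.001 or smaller in both lists, 79 of 126, 284 of 338 and 225 of 303 went the same way, in the same order, which is 62.7%, 84.0% and 74.3% (56.7%, 52.8% and 55.4% from the margins).

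DMRs were found on all 3 classes of scaffold length, and those with small p-values lay more often on short scaffolds than peaks did. Scaffolds ending before 100 kb held 9.5% of peaks, 8.0% of DMRs, 18.7% of DMRs with a p of 0.001 or smaller and 35.0% of those with a q under 0.05. DMR bases per peak base on these scaffolds were lower than on scaffolds ending between 100 kb and 1 Mb in all 6 comparisons, from 0.205 and 0.312 for NF56 against NF50 to 0.414 and 0.491 for NF66 against NF62. On the 20 longest scaffolds, DMR bases per peak base ranged from 0.247 on scaffold_9 to 0.319 on scaffold_3 for NF56 against NF50, and from 0.352 on scaffold_9 to 0.5 on scaffold_5 for NF66 against NF62. Scaffold_9 had the lowest value of these 20 in all 6 comparisons. For NF66 against NF62, between 25.7% and 36.7% of regions were higher at NF66 on each of the 20 scaffolds. The ratios are given without a test.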

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

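The settings added after the data were examined are a q under 0.05, a p of 0.001 or smaller, scaffolds ending at 1 Mb or beyond, a p of 1e-10 or smaller for the counted peaks only, and no repeated names; the others were planned. No paired analysis was possible because the lists pool the 3 libraries of a stage and give no value per library; leaving out each replicate and a replicate block were not run for the same reason. Results on genes, promoters, gene lists and sequence were not run, since no sequence or annotation of the build was used. The depth of the libraries is unknown, so what it limits cannot be stated. Where a cause is not plain from the setting itself (fewer regions kept, a wider overlap asked), the cause was not tested.

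With a p of 1e-10 or smaller, peaks numbered 59858 for NF50, 59958 for NF56, 59266 for NF62 and 55309 for NF66. Asking 50% of a peak to overlap moved the share of peaks found at an earlier stage to 92.7% for NF56 in NF50, 92.9% for NF62 in NF50, 95.1% for NF66 in NF50, 93.5% for NF62 in NF56, 95.6% for NF66 in NF56 and 95.3% for NF66 in NF62, and 50% reciprocal overlap to 91.1%, 91.1%, 92.6%, 91.7%, 92.9% and 92.7% in the same order.

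Peaks gained and lost numbered 4020 and 3806 for NF50 to NF56, 3393 and 4105 for NF56 to NF62, 1992 and 6070 for NF62 to NF66 and 2294 and 6853 for NF50 to NF66 when both lists were held to a p of 1e-10 or smaller, and 165 and 194 for NF50 to NF56, 196 and 157 for NF56 to NF62, 116 and 206 for NF62 to NF66 and 133 and 222 for NF50 to NF66 when only the counted peaks were. Losses still outnumbered gains on the way to NF66 under both. With both lists held to that p, this largely restates that the NF66 list is shorter. It held 55309 peaks, compared with 59266 at NF62 and 59858 at NF50, and its background is unknown.

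DMRs numbered 3 for NF56 against NF50, 8 for NF62 against NF50, 6 for NF66 against NF50, 28 for NF62 against NF56, 14 for NF66 against NF56 and 4 for NF66 against NF62 at a p of 1e-10 or smaller. At a q under 0.05 they numbered 19, 81, 67, 220, 119 and 51, at a p of 0.001 or smaller 2058, 3643, 3836, 4509, 4446 and 4747, and in a peak of either stage 45614, 52442, 53261, 53977, 55354 and 54922, in the same order. Merging within 500 bp kept all counts of peaks and DMRs within 1.5 times. Without repeated names NF62 against NF56 held 98767 DMRs, 60.1% of them higher at NF62.

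The share of DMRs higher at the later stage crossed 50% under 2 settings: in peaks for NF62 against NF50, and at a q under 0.05 for NF66 against NF56. At a p of 1e-10 or smaller it was 0.0% for NF56 against NF50, 75.0% for NF62 against NF50, 33.3% for NF66 against NF50, 53.6% for NF62 against NF56, 35.7% for NF66 against NF56 and 25.0% for NF66 against NF62, of few regions. Counted by bases it was 52.7% for NF62 against NF50, 33.7% for NF66 against NF50, 62.3% for NF62 against NF56, 37.9% for NF66 against NF56 and 26.9% for NF66 against NF62. In a peak it was 44.7% for NF56 against NF50, 47.1% for NF62 against NF50, 30.6% for NF66 against NF50, 54.0% for NF62 against NF56, 33.4% for NF66 against NF56 and 29.7% for NF66 against NF62. On scaffolds ending at 1 Mb or beyond it was 50.2% for NF62 against NF50, 35.6% for NF66 against NF50, 58.5% for NF62 against NF56, 39.3% for NF66 against NF56 and 31.5% for NF66 against NF62. At a q under 0.05 it was 15.8% for NF56 against NF50, 55.6% for NF62 against NF50, 32.8% for NF66 against NF50, 84.1% for NF62 against NF56, 51.3% for NF66 against NF56 and 43.1% for NF66 against NF62. At a p of 0.001 or smaller it was 40.1% for NF56 against NF50, 56.7% for NF62 against NF50, 29.0% for NF66 against NF50, 74.4% for NF62 against NF56, 35.9% for NF66 against NF56 and 18.5% for NF66 against NF62.

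Regions shared by comparisons without a common stage came to 15.7% for NF56 against NF50 with NF66 against NF62, 16.1% for NF62 against NF50 with NF66 against NF56 and 16.0% for NF66 against NF50 with NF62 against NF56 with 50% reciprocal overlap, and to 0%, 12.5% and 33.3% at a p of 1e-10 or smaller, in the same order and from lists of 3, 8 and 6 regions. With a common stage the shares were 26.6% to 32.9% under reciprocal overlap, compared with 35.2% to 42.2%.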

Other observations

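The counts by division of the stages and by single stage, the directions at a p of 0.001 or smaller (between comparisons without a common stage and outside peaks), the tests on lower capture, the placement inside peaks, the neighbours split by peaks and the tests of the stage division were chosen only after the result was seen. Of these, the placement inside peaks was added after the planned placement had given 0.85, because the planned area is itself partly made of DMRs and so sets the chance value high. The test of lower capture on regions outside peaks was added after the one on peak folds had given 1.05, because NF66 has no input library among the labels and a fold over input can shift by 1 factor. Both versions of each are given.

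Of the 3 ways to divide the 4 stages into pairs, the first 2 stages against the last 2 gave the most regions. Of the 422 merged regions with a q under 0.05 in at least 1 list, 148 went the same way in all 4 comparisons of NF62 or NF66 with NF50 or NF56, with directions read from the full lists. Of these, 98 were higher at NF62 and NF66 and 50 lower. The excess of gains held only at that threshold: with a p of 0.001 or smaller, 991 were higher and 986 lower, and over the full lists 2851 were higher and 3690 lower. Among the 98, 31 were at least 2-fold higher in all 4 comparisons of the authors' deposited table, and 24 had no peak at NF50 or NF56, of which 5 had no peak at any stage. Among the 50, 6 were at least 2-fold lower in all 4 comparisons of the authors' deposited table, and 6 had no peak at NF62 or NF66. No DMR was listed between NF50 and NF56 or between NF62 and NF66 for 8 of the 98 and 6 of the 50, so most also had a listed difference within a pair. A q under 0.05 in all 4 comparisons was found for 4 of the 98, for 1 more of them whose largest q rounds to 0.05, and for 1 of the 50. On scaffolds ending before 100 kb lay 44 of the 98 and 12 of the 50. The divisions of NF50 and NF62 against NF56 and NF66, and of NF50 and NF66 against NF56 and NF62, gave 32 and 20 regions. The comparisons across these divisions held 487, 357 and 270 regions with a q under 0.05, in the same order, so they did not start from equal numbers.

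Single stages were counted in the same way, from 3 comparisons that share the libraries of that stage, so these counts cannot be ranked against those of the divisions, which ask for agreement in 4. At NF62, 135 of the 422 regions were higher and 52 lower than at each other stage; of the 16821 merged regions with a p of 0.001 or smaller in at least 1 list, 3304 were higher and 974 lower, and over the full lists 12945 and 4531. At NF66 the balance was the opposite, with 36 higher and 72 lower, 900 and 3654, and 4650 and 13942 in the same order. NF56 had 34 higher and 116 lower at a q under 0.05, but 1208 and 1664 at a p of 0.001 or smaller and 5736 and 6102 over the full lists. NF50 leaned to higher as NF62 did, with 52 higher and 24 lower, 1616 and 968, and 7611 and 4232 in the same order.

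The division between the first 2 stages and the last 2 may follow metamorphic stage, and 1 technical explanation could be set against it. If repeated sequence on short scaffolds alone made the pattern, it would be absent on scaffolds ending at 1 Mb or beyond, where the count at a p of 0.001 or smaller was 1.83 times the higher of those for the 2 other divisions. No sequence was used, so repeated sequence on longer scaffolds is not covered by this ratio and stays open. Over all scaffolds this ratio was 1.88 (1977 against 1053 and 838; 6541, 4022 and 3758 over the full lists), but the division was singled out because it gave the most, and 1 of 3 divisions is always the largest, so the ratio does not tell stage from a chance likeness of any 2 stages. Between comparisons with no library in common, 84.0% of the shared regions at that p had the same direction for NF62 against NF50 with NF66 against NF56, 74.3% for NF66 against NF50 with NF62 against NF56, and 62.7% for NF56 against NF50 with NF66 against NF62 (52.8%, 55.4% and 56.7% from the margins), a result that any likeness within the pairs of stages would also give. The labels give no batch, so libraries of the first and last stages prepared or sequenced apart, animals of different clutches, and lower capture at the later stages stay open beside stage itself. The median fold at shared peaks was 0.917 and 0.899 at NF62 and 0.962 and 0.943 at NF66 of that at NF50 and NF56. Over the full lists, regions outside all 4 peak lists were mostly higher at NF62 (57.5% against NF50 and 66.5% against NF56) but not at NF66 (42.1% and 47.8%).

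Most listed regions were lower at NF66, and a scaling difference between libraries may account for it. A single scaling difference between the NF66 libraries and the others would leave regions mostly lower at NF66 both inside and outside peaks, and outside all peaks this was so in 3 of the 3 comparisons, though the share higher at NF66 was lower inside than outside (30.6% and 42.1% against NF50, 33.4% and 47.8% against NF56, 29.7% and 31.4% against NF62). With a p of 0.001 or smaller, the share higher at NF66 outside peaks was 57.4% against NF56, 45.1% against NF50 and 18.8% against NF62. Lower capture of methylated DNA at NF66 as the only cause would make regions outside peaks mostly higher at NF66, and over the full lists this was so in 0 of the 3 comparisons; the median ratios of the NF66 fold at shared peaks, 0.962 to NF50, 0.943 to NF56 and 1.05 to NF62, decide nothing, since the NF66 background is unknown. Scaling, lower capture together with scaling, and a loss of methylation at the end of metamorphosis all stay open, since no count per library was analysed here.

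The p-values were nearly even for NF56 against NF50 and in excess at small values in the 5 other lists, and it was tested whether most listed regions may carry no difference between stages. Regions 1 to 5 kb apart shared a direction more often than shuffled directions gave, by a median of 4.61 percentage points over the 6 lists (3.42 to 5.18). The bound set for no difference was an excess of 2 points or less in at least 4 of the 6 lists. The bound set against it was over 5 points in at least 4. Neither was met, with 0 lists at 2 points or less and 2 lists over 5. Split by peaks, the excess was over 5 points in 5 of the 6 lists for regions in a peak and in 4 of the 6 outside all peaks, past the bound set for all regions, but neighbours may also share chance deviations of a library, so this excludes nothing. Comparisons without a common stage shared a median of 0.85 times the regions of random placement, which met the bound of 1.1 set for no difference before the data were examined, and 1.13 times inside peaks, between the bounds of 1.1 and 1.5. Directions of the shared regions were the same in 58.4% for NF62 against NF50 with NF66 against NF56 (49.6% from the margins). They were the same in 56.4% for NF66 against NF50 with NF62 against NF56 (47.3%). For NF56 against NF50 with NF66 against NF62 the share was 51.3% (52.6%). The higher shares argue against chance alone for those shared regions, though a batch would also give them. The share of true differences in the lists stays open, and with it how far the listed directions speak for the genome.

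The 143 listed DMRs with a q under 0.05 and a fold under 1.5 merged across lists into 105 regions, of which 46.7% (49, exact binomial 95% interval 36.9% to 56.7%) lay on scaffolds ending before 100 kb, as did 9.5% of peaks. DMRs with a q under 0.05 and a larger fold merged separately into 342 regions, with 28.1% on such scaffolds; 25 of the 105 overlap one of these, and of the other 80, 41.2% (30.4% to 52.8%) lay there.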
